A study of Homo sapiens with 2 samples.

How the data were processed

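Total RNA of 2 human cell cultures was profiled, each on 1 array. The MDA-231 group (MDA-MB-231, an established triple-negative breast cancer line) and the MDA-231-Gem group (its gemcitabine-resistant subline) each hold 1 sample, so the comparison has no replicates. Per the labels' protocols, the subline was selected with rising gemcitabine concentrations, RNA was purified with a miRNA isolation kit, and the miRNA was labelled with Cy3. The arrays were 1-colour Agilent human miRNA arrays on 1 slide, and both were read in the same scan, so slide and scan do not separate the groups.

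The authors deposited the scanner output of each array as intensity values per spot, made with Agilent Feature Extraction 10.7, per the submitters' processing notes. Per the file headers, the protocol subtracted background with spatial detrending, and the array design was built on hg19. The processed intensity of a spot can be negative and carries no scaling between arrays. The authors' deposited value table held the same processed intensity, unlogged: all 62944 values of each array lay within 0.51% of the scanner value, as rounding to 3 significant digits allows. Its column medians were 0.84 for MDA-231 and 1.05 for MDA-231-Gem. A further deposited table held log2 values per miRNA that its name describes as quantile normalized by the authors. Above its floor this table followed log2 of the Feature Extraction summary per miRNA (Pearson r across entries 1.0 for MDA-231 and 0.984 for MDA-231-Gem). It listed 1711 of 2047 entries of MDA-231 and 1670 of MDA-231-Gem at floors of -3.27 and -3.32. Its columns thus did not share 1 set of values, unlike the probe means in the quantile setting used below. The software behind that normalization is not given in the sources used here.

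Each array held 62944 spots, of which 60780 were not controls and belonged to 4945 probes of 2026 entries. Of these entries 1887 carried human and 139 viral miRNA names. Names are those of the array design and are partly old. Spots flagged as non-uniform or population outliers were left out, which removed 7.1% of the non-control spots of MDA-231 and 5.61% of MDA-231-Gem. No spot was saturated (0 on each array). Spots of a probe were averaged, and the signal of a miRNA was the sum over its probes. Signals were scaled by each array's 75th percentile over probes detected on both arrays (187.9 units for MDA-231, 204.1 for MDA-231-Gem) and then taken to log2. A probe was called detected where more than a share of 0.5 of its unflagged spots was marked well above background, and a miRNA where at least 1 of its probes was. Differences are MDA-231-Gem minus MDA-231 on this log2 scale.

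With 1 array per group no p-value can be computed, and size was the only criterion: a 2-fold difference among entries detected on both arrays. The standard error (SE) given with a difference comes from the 24 to 30 spots per entry and array. It covers spots within an array only and leaves out the spread between cultures, RNA extractions and labellings. For an entry detected on 1 array only, the difference is set against the higher of its own signal and the lowest detected signal of the other array. Set against the lowest detected signal, it is a lower bound. Set against its own signal, it is the ratio of the measured signals, which lay below 1 for some entries. Both kinds are called bounds here. On the array where it was not detected, such an entry was not well above background.

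Before the data were examined, 23 lists of miRNAs with 306 names were fixed, of which 289 matched an array entry, older names included where they were unambiguous. For lists with at least 3 members detected on both arrays, the median difference was ranked among 10000 random lists of the same size, matched on mean log2 signal in 10 bins. This percentile describes these arrays and is not a test across conditions. The rule for named miRNAs was also fixed before the data were examined. It takes the 8 highest and 8 lowest differences among the entries at or above the median of the mean signal, and the 3 highest bounds per array. It also takes up to 4 members of each list with the largest differences (of lists with fewer than 3 members detected on both arrays, each detected member), miR-21-5p, and the 5 brightest entries per array. Names outside the rule are marked as chosen after their values were seen.

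The steps were tested on simulated arrays of 2026 entries with 20 entries changed at each of 1.5-fold, 2.5-fold and 4-fold. At 2.5-fold and at 4-fold, only 9 of the 20 entries were detected on both simulated arrays, and 9 of 9 were called at the 2-fold limit. All changed entries had been drawn from those detected on both real arrays. The check thus left out many dimmer entries that count as detected in the data. At 1.5-fold, 0 were called, and of 106 unchanged entries detected on both arrays 0 were called. Both simulated arrays were built from the MDA-231 probe means with noise between spots only. Spread between cultures, extractions and labellings was left out, so the simulation checks the computation and says nothing about false calls between cultures. Of 100 lists without a shift, drawn at random, 5 fell outside the central 95% of random lists. This does not cover lists whose members vary together.

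Alternatives covered the scaling (75th percentile over all non-control probes, quantile, median, none), normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), the summary over probes, the deposited tables, the detection filter and the fold limit. Normexp was run on the median spot signal, in place of the mean named in the plan. Scaling by labelling spike-ins, keeping all spots and 1 common detection limit were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Gene neighbourhood came from a RefSeq table of assembly GRCh38.p14, used for names and neighbours only, since the array design has another build. Of the 235 human entries detected on both arrays, 204 matched 1 gene, 22 matched several and 9 matched none.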

Results

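The miRNA content of the breast cancer line MDA-231 was compared with that of MDA-231-Gem, a subline made resistant to gemcitabine, a deoxycytidine analogue that blocks DNA synthesis. The series asks which miRNAs differ between the resistant and the parental cells. Each group had 1 array, both from cells in logarithmic growth, and no replicates. Of 2026 entries on the array, 250 were detected in MDA-231 (with 9.26% of all probes detected) and 288 in MDA-231-Gem (11.0% of probes). Negative control spots averaged 0.07 ± 3.24 units (SD over 933 spots) in MDA-231 and 0.59 ± 3.2 units (SD over 937 spots) in MDA-231-Gem. The lowest detected miRNA signals were 18.1 and 17.9 units, on another scale, since a miRNA signal sums the means of its probes. They are no strict limit, as miR-486-5p went undetected at 28.4 and 27.5 units. The brightest 5 entries were the same in both groups, namely miR-4454, miR-21-5p, miR-720, let-7a-5p and miR-29a-3p. Across the 244 entries detected on both arrays, log2 signals correlated with Pearson r = 0.968, where entries are not independent replicates.

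In MDA-231-Gem, miR-146a-5p, an NF-kappaB-induced regulator of inflammatory signalling, was 5.18-fold higher than in MDA-231 (log2 difference 2.37 ± 0.015, SE over spots). The p53-induced miR-34a-5p was 3.61-fold higher (1.85 ± 0.062). Both miRNAs of the X-linked cluster of miR-221 and miR-222, which target the cell cycle inhibitor p27, were higher, miR-222-3p by 3.04-fold (1.60 ± 0.016) and miR-221-3p by 2.42-fold (1.28 ± 0.009). Among the 122 entries at or above the median signal (the brighter entries), the other miRNAs that stood out upward were miR-224-5p at 2.72-fold, miR-3651 at 2.53-fold, miR-374a-5p at 2.30-fold and miR-374b-5p at 2.24-fold. In the opposite direction, miR-130b-3p was 2.14-fold lower in MDA-231-Gem (-1.10 ± 0.023). The proliferation-linked miR-18a-5p of the miR-17-92 cluster was 2.10-fold lower (-1.07 ± 0.029). Smaller differences were seen for miR-29b-1-5p (1.97-fold lower), miR-331-3p (1.91-fold lower), miR-378a-3p (1.73-fold lower), miR-107 (1.70-fold lower), miR-17-5p (1.65-fold lower) and miR-130a-3p (1.62-fold lower). With normexp background correction, several log2 differences were smaller, at 0.95 for miR-34a-5p, 0.89 for miR-224-5p, 0.58 for miR-374a-5p, 0.55 for miR-374b-5p, -0.63 for miR-18a-5p and -0.37 for miR-29b-1-5p.

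**Figure D1:**
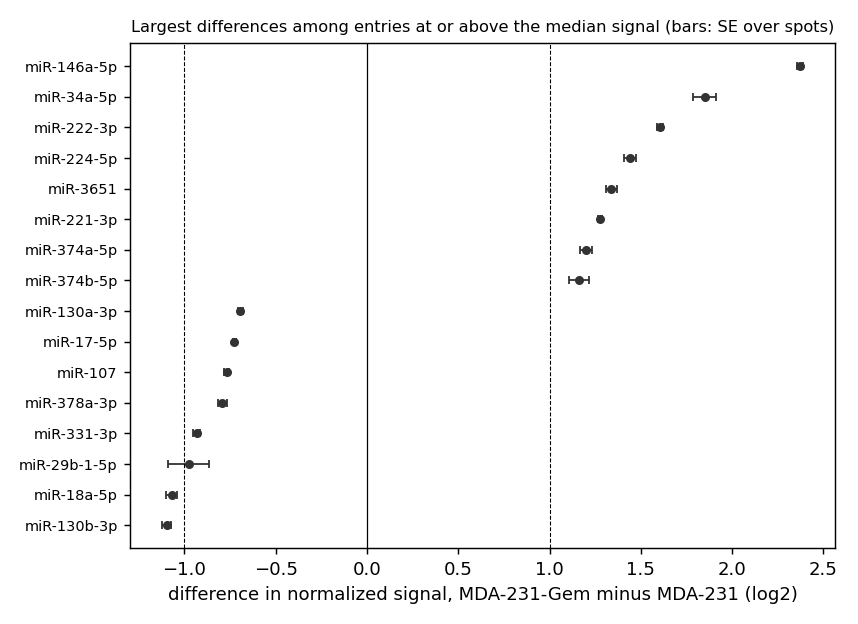
Differences in normalized signal, MDA-231-Gem minus MDA-231 (log2, horizontal axis), of the 8 highest and 8 lowest of the brighter entries. Points are single-array differences, bars are SE over spots within arrays, and dashed lines mark 2-fold. miR-146a-5p lies farthest out at 2.37, and the lowest point is miR-130b-3p at -1.10.

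By size alone, 16 of the 244 entries were at least 2-fold higher in MDA-231-Gem, 7 were at least 2-fold lower and 221 lay within 2-fold. No viral-named entry was among those 2-fold apart (0 of 9 detected on both arrays). The higher entries included, besides those above, miR-221-5p (3.51-fold), miR-1290 (3.31-fold), miR-3656 (2.18-fold), miR-34b-5p (2.09-fold), miR-34c-5p (2.07-fold) and miR-181a-5p (2.06-fold). With normexp, whose offset by itself shrinks the differences of dim entries, none of these 6 stayed 2-fold higher. Log2 differences were 0.66 for miR-221-5p (1.81 in the main result), 0.46 for miR-1290 (1.73), 0.46 for miR-3656 (1.13) and 0.80 for miR-181a-5p (1.04). The remaining pair, miR-7-5p (3.56-fold) and miR-455-3p (3.06-fold), was named after its values were seen. Beyond miR-130b-3p and miR-18a-5p, the lower entries were miR-18b-5p (2.5-fold lower) and, named after their values were seen, miR-532-5p (2.36-fold lower), miR-128 (2.14-fold lower), miR-660-5p (2.11-fold lower) and miR-185-5p (2.01-fold lower). The largest SE over spots among these 23 entries was 0.13. These differences have no replicate check, and no p-value can be given.

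The split of higher against lower entries depended on how the arrays were scaled. The main scaling left a median difference of 0.11 over the 244 entries (0.23 unscaled), so that 69.6% of the entries 2-fold apart were higher. The 75th percentile over all probes gave 13 higher and 9 lower (59.1% higher), as did median centring. Quantile normalization gave 12 and 10 (54.5%), the values of the authors' deposited normalized table gave 15 and 11 (57.7%), and no scaling 18 and 2 (90%). Scaling by the labelling spike-ins, added after seeing the data, gave 42 and 0 (100%). Keeping flagged spots, also added later, gave 16 and 12 (57.1%), and normexp background correction gave 3 and 0 (100%). The 8 highest and 8 lowest of the brighter entries kept their direction in each of these settings.

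**Figure D2:**
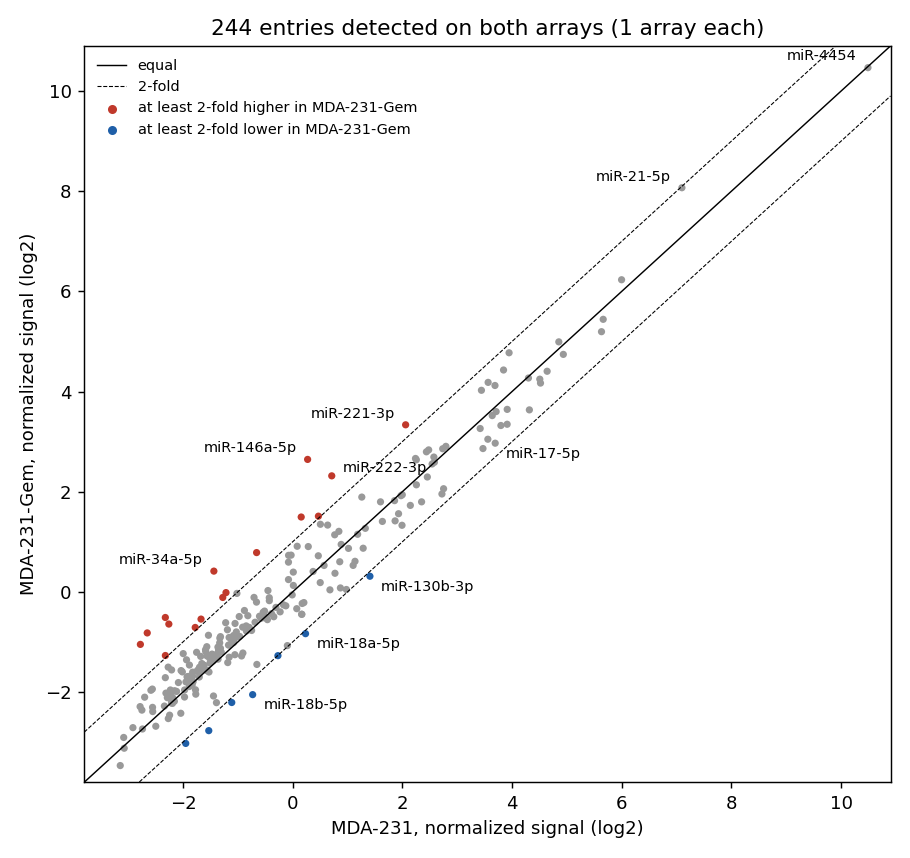
Normalized log2 signal in MDA-231 (horizontal axis) and MDA-231-Gem (vertical axis) of the 244 entries detected on both arrays, 1 array per group. Dashed lines mark 2-fold. The 16 entries in red lie at or above the upper line and the 7 in blue at or below the lower line, with miR-146a-5p farthest above at 2.37.

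Abundant and often tied to gemcitabine response, miR-21-5p was chosen for its own comparison before the data were examined. Its signal was 25720 units in MDA-231 and 54820 in MDA-231-Gem, the second brightest entry of both arrays. After scaling it was 1.96-fold higher in MDA-231-Gem (0.97 ± 0.011, SE over spots), just under the 2-fold limit. The difference was 0.08 under quantile normalization, which gives the brightest probes of both arrays nearly equal values by rank. In the other settings it lay between 0.78 in the authors' deposited normalized table and 1.45 with scaling by the labelling spike-ins.

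Of the 13 miRNA lists that could be ranked, 6 had medians outside the central 95% of random lists. For lists whose members vary independently, 0.65 would be expected. Members of a cluster or family can vary together, so such lists may fall outside more often, and 0.65 may be too low a reference. Lists also share members, so the 6 are not separate observations. All 12 detected members of the miR-17-92 cluster and its paralogous clusters, which promote cell proliferation, were lower in MDA-231-Gem, with a median of -0.57 that lay below all 10000 random lists. The 9 members outside the MIR106B locus ranged from -1.32 (miR-18b-5p) to -0.53, with miR-18a-5p at -1.07, miR-17-5p at -0.72 and miR-17-3p at -0.64 (with normexp, miR-18b-5p was at -0.42 and miR-17-3p at -0.23). The 3 of the MIR106B locus (miR-106b-5p, miR-93-5p and miR-25-3p, named after their values were seen) lay between -0.06 and -0.04. The direction of these 3 turned without scaling, to between 0.06 and 0.08, and with labelling spike-ins, to between 0.42 and 0.44. The other 9 stayed lower under both, though with labelling spike-ins their median was -0.13 and their highest value -0.05, against a median of -0.61 in the main result. Several miRNAs of this list are nearly identical in sequence, such as miR-18a and miR-18b, and their signals may be shared.

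The 3 detected arms of the miR-221 and miR-222 cluster were all higher, with a median of 1.60 at the 99.48 percentile of random lists. Of the 6 p53-linked miRNAs detected on both arrays, 4 were higher and 2 lower, with a median of 0.91 at the 99.89 percentile. A further 1 was detected only in MDA-231-Gem. The miR-34 genes, known as direct p53 targets, gave the higher values with miR-34a-5p at 1.85, miR-34b-5p at 1.07 and miR-34c-5p at 1.05. miR-192-5p followed at 0.77. The activity of p53 was not measured, so these values do not show a p53 response. The 2 lower members were the paralogs miR-107 at -0.77 and miR-103a-3p at -0.51, the latter named after its value was seen. Among the brighter entries this list kept 3 members and its median was -0.51. With normexp the median over all 6 was 0.21 (98.7 percentile), with miR-34b-5p at 0.41, miR-34c-5p at 0.27 and miR-192-5p at 0.15. All 5 detected members of the miR-23/27/24 clusters were higher, from 0.42 to 0.63, with a median of 0.58 at the 97.81 percentile. miR-23b-3p (0.63), miR-23a-3p (0.62), miR-27a-3p (0.58) and miR-24-3p (0.43) gave similar values, though signals of near-identical members such as miR-23a and miR-23b may be shared, and the list's median stayed above 0 under each scaling. It lay outside the central 95% in 13 of 15 settings, and not with normexp (96.93 percentile) or with all spots kept (96.18). Among the 13 are the main setting, the scalings by 1 factor and the deposited value table, where the percentile could not move.

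The miR-130, miR-301, miR-148 and miR-152 families had a median of -0.44 at the 1.92 percentile over 4 members, which was 0.04 with scaling by the labelling spike-ins. This list lay outside the central 95% in 9 of 14 settings, and not in the authors' deposited normalized table (7.4 percentile), with the Feature Extraction summary (5.8), with the mean over probes (4.0), without a detection filter (6.9) or with all spots kept (3.98). The 9 include the main setting, the scalings by 1 factor and the deposited value table, where the percentile could not move. Of the settings that could move it, only quantile normalization, normexp and Feature Extraction's own detection call left it outside. Within them miR-130b-3p (-1.10) and miR-130a-3p (-0.69) were lower, miR-301a-3p stood at -0.19 and miR-148b-3p at 0.62. The 14 drug-response miRNAs detected on both arrays, collected for reported ties to chemotherapy response, had a median of 0.38 at the 98.93 percentile (0.16 with normexp). A further 2, miR-200b-3p and miR-218-5p, were detected only in MDA-231-Gem. Their list lay outside the central 95% in 12 of 15 settings, again counting those that could not move its percentile. Of the 14 miRNAs, 9 were higher and 5 lower, and 4 were at least 2-fold higher (miR-146a-5p, miR-34a-5p, miR-222-3p and miR-221-3p), which the lists above also hold in part.

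**Figure D3:**
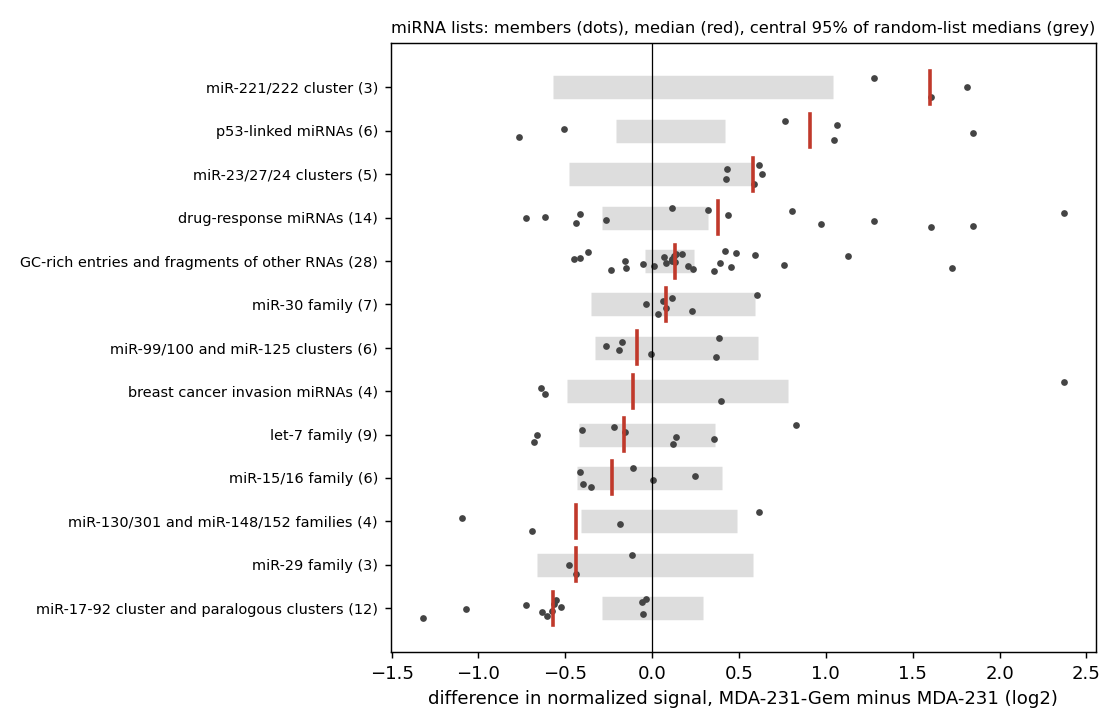
Differences in normalized signal, MDA-231-Gem minus MDA-231 (log2, horizontal axis), of list members detected on both arrays, with the number of members in parentheses. Dots are members, red lines are list medians, and grey bars span the central 95% of medians of 10000 random lists matched on signal. The miR-17-92 list has its median at -0.57 and the cluster of miR-221 and miR-222 at 1.60, both outside their grey bars.

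The other 7 ranked lists lay within the central 95% of random lists, and the direction of each one's median turned with the scaling or another setting. Of these the breast cancer invasion list lay outside in 1 of 15 settings, among the brighter entries (3 members, median -0.61, 2.19 percentile). The tumour-suppressive let-7 family had a median of -0.16 over 9 members that went both ways, with let-7i-5p at 0.83, let-7b-5p at -0.68 and let-7c at -0.66. All 3 members of the collagen-targeting miR-29 family were lower (median -0.44), but higher or at 0.0 with labelling spike-ins. Medians were 0.08 for the miR-30 family (7 members), -0.23 for the miR-15/16 family (6 members) and -0.09 for the miR-99, miR-100 and miR-125 clusters (6 members). The breast cancer invasion list had a median of -0.11 over 4 members, with miR-146a-5p at 2.37, miR-138-5p at -0.64, the hypoxia-induced miR-210 at -0.61 and miR-126-3p at 0.40. Entries that are GC-rich or fragments of other RNAs had a median of 0.13 over 28 members, including miR-1290 at 1.73, miR-3656 at 1.13 and miR-1246 at 0.76 (0.46, 0.46 and 0.50 with normexp). Lists with too few detected members gave single values, which were 1.04 for miR-181a-5p, 0.32 for miR-181b-5p, 0.58 for miR-494 of the 14q32 cluster and 0.40 for the endothelial marker miR-126-3p.

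Detection itself differed, with 44 entries detected only in MDA-231-Gem and 6 only in MDA-231. Most lay near the detection limit: the bound reached 2-fold for 4 of the 44 and 1 of the 6. miR-142-3p, a blood cell miRNA, was at least 9.99-fold higher in MDA-231-Gem (196.7 against 2.14 units). The epithelial miR-200b-3p was at least 5.22-fold higher (102.8 against 6.09 units) and miR-218-5p at least 3.72-fold higher. The fourth, miR-135b-5p at 2.99-fold or more, was named after its value was seen. In MDA-231, miR-551b-3p was at least 15.9-fold higher than in MDA-231-Gem (262.3 against 1.82 units). For miR-362-5p and miR-484 the values were 1.93-fold and 1.70-fold. These are ratios of measured signals, since both lay above the lowest detected signal in MDA-231-Gem. With 1 common limit on median-centred signals, added after seeing the data, the counts were 33 and 23.

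Marker lists of other cell types were mostly undetected. Of the 7 blood cell markers, miR-142-3p and miR-223-3p were detected only in MDA-231-Gem, the latter at 30.3 against 26.2 units, and the other 5 in neither group. Of the 9 miR-200 family members and the 7 epithelial and luminal markers on the array, miR-200b-3p alone was detected, and only in MDA-231-Gem. No fibroblast or smooth muscle marker (0 of 6), liver, muscle or neural marker (0 of 8), pluripotency miRNA (0 of 9) or chromosome 19 cluster miRNA (0 of 33) was detected on either array. Of the 50 listed miRNAs of the 14q32 cluster, 49 were detected in neither group. The list does not hold every arm of the cluster. One left out, miR-431-3p, named after its value was seen, was detected on both arrays (197.9 units in MDA-231, 161.8 in MDA-231-Gem).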

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

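The values and tests of this part were all chosen after the controls had been seen. Among the control probes, which enter no comparison of miRNAs, the labelling spike-ins differed between the arrays (the spike-in roles are those of the quality metrics per the file headers). Without scaling, dmr_285 stood at -0.43 (log2, MDA-231-Gem minus MDA-231) and dmr_31a at -0.29. Controls whose role is not given in the sources used here went both ways, with mr_1 at -0.43, hur_5 at -0.22, hur_4 at -0.06, hur_2 at 0.01, hur_1 at 0.06 and hur_6 at 0.20. The hybridization spike-ins dmr_3 and dmr_6 were at -0.05 and -0.04, so the difference did not extend to them.

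A lower labelling yield in the MDA-231-Gem reaction as the only difference would have lowered the miRNAs along with the spike-ins, to -0.29 or less. Their unscaled median was 0.23 (bootstrap interval over entries 0.19 to 0.26), which argues against it. More miRNA per amount of spike-in, from a larger input or from a higher miRNA content of the resistant cells, stays open: relative to the labelling spike-ins, the median entry was 0.59 higher in MDA-231-Gem. Input and content cannot be told apart, since the labels used here give no input amounts. A general difference in miRNA content between the lines was not tested.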

How the results depend on the processing

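No p-value, leave-one-out or paired result exists with 1 array per group. No paired analysis was possible because each group has a single sample. Counts are given as higher/lower at 2-fold, against 16/7. Scaling by 1 factor shifts all entries by a constant, so counts moved with it: no scaling gave 2 lower, and labelling spike-ins (chosen after seeing the data) 42/0. The authors' deposited table gave 11 lower and keeping all spots (also chosen later) 12 lower; the cause was not tested. Normexp gave 3/0. Its offset of 50 units per spot by itself draws the log2 differences of dim entries towards 0. The background model and the median spot signal changed along with the offset, and their parts were not separated. By construction, no detection filter gave 155/80 among 828 entries, the 122 entries at or above the median signal 9/2, the 1.5-fold limit 38/22 and the 3-fold limit 7/0. In the deposited table, 14 of the 16 higher and 7 of the 7 lower entries were shared with the main result; with all spots kept, 10 and 7 were.

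The miR-21-5p difference of 0.97 became 0.85 with the 75th percentile over all probes, 0.86 with the median, 1.09 without scaling, 1.45 with spike-ins, 0.90 with the Feature Extraction summary, 0.78 in the deposited table, 0.80 with all spots and 0.08 with quantile normalization. Its brighter probe ranked 3 on both arrays, so quantiles equate it. Lists outside the central 95% fell from 6 of 13 to 3 of 11 among these brighter entries, which hold fewer members; there the p53-linked median reversed to -0.51, without miR-34b-5p, miR-34c-5p and miR-192-5p. The median of the miR-130, miR-301, miR-148 and miR-152 families reversed to 0.04 with spike-ins, by their constant shift. The counts of settings that follow include some that could not move a list's percentile. These are the main setting, the scalings by 1 factor (labelling spike-ins included) and the deposited value table, which repeats the same intensities. The miR-17-92 list stayed outside in 15 of 15 settings (medians -0.75 to -0.09) and miR-221 with miR-222 in 14 of 14 (1.18 to 2.08). The p53-linked list was outside in 14 of 15 (median 0.21 with normexp), the miR-23/27/24 clusters in 13 of 15, the drug-response list in 12 of 15 (percentiles of 95.54 with quantiles, 97.0 with normexp and 93.0 among the brighter entries) and the miR-130, miR-301, miR-148 and miR-152 families in 9 of 14. Of the 6 lists outside in the main setting, the 2 changes of sign above were the only ones; the median of each of the other 7 lists changed sign in at least 1 setting.

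Detection depended on the rule. Feature Extraction's own detection call gave 53 only in MDA-231-Gem and 12 only in MDA-231. At least 1 bright spot gave 439 and 437 detected, with 115 only in MDA-231-Gem and 117 only in MDA-231, and 1 common limit (chosen later) gave 33 and 23. No bound can rest on a signal below the lowest detected ones, near 18 units.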

Other observations

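All tests of this part were chosen after the differences had been seen. The following miRNAs were grouped after their values were seen, and no test of these groups was run. The 5 detected miR-320 members (miR-320a to miR-320e) were all higher in MDA-231-Gem, from 0.67 to 0.84, and share much of their sequence, so their probes may not measure them apart (1.62-fold for miR-320b, 1.79-fold for miR-320d). Of one miRNA cluster on the X chromosome, miR-532-5p stood at -1.24 and miR-660-5p at -1.08. Detected only in MDA-231 were miR-362-5p, with a ratio of measured signals of 1.93-fold, and miR-532-3p, with a bound of 1.5-fold.

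miR-200b-3p reached 102.8 units in MDA-231-Gem, and its cluster partners miR-200a-3p and miR-429 stood at 13.9 and 14.4 units, below detection, against -1.4 and -0.6 in MDA-231. The other arms miR-200a-5p and miR-200b-5p stood at 1.0 and 0.9 units in MDA-231-Gem (3.2 and -0.7 in MDA-231). miR-200c-3p and miR-141-3p, from another locus, stood at 2.4 and 1.5 units in MDA-231-Gem. A difference between the loci was not tested. Of the viral-named entries, 9 were detected on both arrays, with a median difference of 0.22, a range of -0.20 to 0.55 and signals of up to 142 units. The SD of their differences was 0.26, against 0.55 for 100 human entries in the same signal range. Whether signals in this range, that of miR-200b-3p included, are specific to the named miRNA was not tested.

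For 32 pairs of detected miRNAs with different name numbers whose genes lie within 10 kb, the median distance between their differences was 0.20, against 0.45 in reshuffled data. A distance as small came up in 44 of 10000 reshuffles, a description of these arrays and not a p across conditions. Without the pairs of the miR-17-92 and miR-23/27/24 lists, 17 pairs gave 0.21, matched in 290 of 10000 reshuffles, and these still hold the miR-221 and miR-222 pairs already described. Shared transcription or copy number of neighbouring genes stays open, since the distance restates the pattern and does not test what lies behind it. The 17 hairpins with both arms detected gave a larger distance of 0.36, as small in 2656 of 10000 reshuffles, so arms of a hairpin did not stand out as closer than other pairs.

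The excess of entries detected only in MDA-231-Gem (44 against 6) was set against array-wide brightness around the detection limit. With 1 common limit on median-centred signals the counts were 33 and 23, a ratio of 1.43. This does not decide, since centring can by itself draw the counts together and the limit was changed along with it. Brightness and a real gain of low-abundance miRNAs in the resistant cells, which was not tested, both stay open.

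Carry-over of RNA from whole blood or serum, weighed for miR-142-3p, miR-200b-3p and miR-218-5p (bounds of 3.72-fold or more in MDA-231-Gem), would bring the abundant blood miRNAs along. Of the other 6 blood cell markers, 0 were both detected and raised by over 3 standard errors. With miR-451a at 4.7 units and miR-486-5p at 27.5 (28.4 in MDA-231), this argues against carry-over from whole blood or serum. It does not speak to other sources of miR-200b-3p and miR-218-5p, which are not among the blood cell markers. Below detection and so not counted, miR-142-5p from the same hairpin as miR-142-3p stood at 6.4 ± 0.9 units (SE over spots) against -1.7 ± 1.8 in MDA-231. A minor admixture of another line would by itself leave no parental miRNA over 2-fold lower. Of the 7 entries at least 2-fold lower and the 1 with such a bound, 3 passed 2-fold (miR-130b-3p, miR-18b-5p and miR-551b-3p). They did so by more than 3 standard errors over spots or by their bound, and made up 1.2% of the miRNAs detected in MDA-231. This count cannot decide, since the resistant cells may have lost miRNAs of their own with or without an admixture. Admixture cannot be told apart from a change in the resistant cells themselves, which was not tested.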
